A study of Mus musculus with 4 samples.

How the data were processed

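Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in a mouse pancreatic beta cell line, per the labels, with antibodies to Insm1, Neurod1 and Foxa2 and with control IgG. The 4 samples each form a group of 1. A deposited site list was used for each of the 3 factors, and no site list of the IgG sample was used here. The series design text counts 6 samples, with repeats of the Insm1 and Foxa2 pull-downs; how repeats entered the lists is not given in the sources used here. No spread between replicates can therefore be had. Every interval and p-value below describes sites within 1 list per factor and covers counting error or placement only.

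Per the submitters' processing notes, CASAVA, Bowtie 0.12.7 and MACS 1.4 were used with the mm9 build of the mouse genome. The settings, the threshold for a site, the control and any filtering are not given in the sources used here. The deposited lists have no header. Each line holds a chromosome, a start, an end, a position inside the site and a whole number. The inner position always lies between start and end and was read as the summit. The whole number is treated as the authors' site score of unknown definition, and was used only to rank, split or describe sites within a list, never to compare levels between lists. Coordinates are given as deposited. Sites lie beyond the last gene end of the GRCm38 gene table on 10 of 20 chromosomes, so that table was not used to place sites. The read depth of each library is unknown, since the lists give no counts of reads.

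A site was called shared when it overlapped a site of the partner list by at least 1 bp. Regions are the merged union of all sites of the 3 lists. Shared numbers were tested with a one-sided permutation test of 10000 random placements, in which the Neurod1 and Foxa2 lists were each moved by a random circular offset per chromosome, within the span from the first to the last site. The association of the partners within a list was tested with Fisher's exact test, two-sided as were the McNemar and binomial tests. Scores of classes of sites were compared by a two-sided permutation test of mean ranks with 100000 resamples, or 10000 for alternative settings, with Benjamini-Hochberg adjustment over the 9 class comparisons. Shares carry 95% Wilson intervals, and odds ratios carry 95% intervals on the log scale. Medians and rank correlations carry 95% bootstrap intervals from 2000 draws. Shares of Insm1 sites with one or the other partner were compared by an exact McNemar test. Summit distances were set against 10000 permutations of the relative summit positions among the shared partner sites. Sites were treated as independent, which neighbouring sites may not be.

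The alternatives fixed before the data were examined were centres within 100 bp, sites widened by 500 bp on both sides, the sites scoring above the median of each list, local moves of 10 to 100 kb, and, for Insm1 scores, terciles of site width. Lists of equal length, the Foxa2 or Insm1 list alone limited to the length of the Neurod1 list, removal of sites of at most 60 bp, deciles of the Insm1 score, the alternatives for Neurod1 and Foxa2 scores, the alternatives for sites with neither partner, the score classes with a single partner, the associations within the Neurod1 and Foxa2 lists, the comparison of the Neurod1 and Foxa2 shares, sharing by score decile, summit distances, score correlations and the X chromosome were added after the data were seen. Sites are named by a rule fixed before the data were examined: the 5 highest-scoring Insm1 sites with both partners and the 5 highest-scoring sites of each list. Planned comparisons that need genes, transcription starts or motifs were not run, because no mm9 genome or annotation was used here, so sites are given by position and not by gene. The parts of the rule that name genes were dropped for the same reason.

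The scripts were tested with simulated partner lists and with scores drawn at random from the Insm1 list. With Insm1 sites set against random Neurod1 lists, 1 of 40 tests fell at or under 0.05. With a planted share of 40%, 40.0% of the 17453 Insm1 sites of the deposited list were found shared. The planted sites were copies of Insm1 sites, moved by less than the narrowest Insm1 width of 52 bp. Their recovery was therefore certain and tests the counting only. Of 100 rank tests with no score difference, 4 fell at or under 0.05. The analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.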

Results

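Genome-wide binding of the transcription factors Insm1, Neurod1 and Foxa2 was mapped by ChIP-seq in a mouse beta cell line. The line was derived from pancreatic islets of RIP1-Tag2 mice, in which an insulin promoter drives a viral oncogene in beta cells. The mice were 6 weeks old, and cells of passages 10 to 15 were grown in 25 mmol/l glucose. Insm1 is a zinc finger protein of endocrine and neuronal cells, Neurod1 is a basic helix-loop-helix factor that binds E-boxes, and Foxa2 is a forkhead factor. The title of the series names cooperation of Insm1 with Neurod1 and Foxa2, so the main comparison is whether the sites of the 3 factors coincide. There was 1 site list per factor and no replicate, and the IgG control enters no comparison.

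The lists held 17453 Insm1 sites, 14607 Neurod1 sites and 28379 Foxa2 sites on the mm9 genome. Sites were narrow, with a median width of 175 bp for Insm1, 147 bp for Neurod1 and 199 bp for Foxa2. Neurod1 sites were under 100 bp wide in 22.2% of cases, compared with 3.8% for Insm1 and 6.9% for Foxa2. Scores started at 76 in the Insm1 list, 46 in the Neurod1 list and 19 in the Foxa2 list, with medians of 130, 72 and 42. The scale of the scores is not defined in the sources used here, and they were compared only within a list. The number of reads behind a site is unknown.

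Most Insm1 sites were also sites of a partner factor. Of the 17453 Insm1 sites, 9593 (54.96%, 95% Wilson interval 54.23 to 55.7%) overlapped a Neurod1 site and 9816 (56.24%, 55.51 to 56.98%) overlapped a Foxa2 site. Both partners were present at 6623 Insm1 sites (37.95%), Neurod1 alone at 2970 (17.02%), Foxa2 alone at 3193 (18.29%) and neither at 4667 (26.74%). Random placement of the partner lists gave a mean of 34.41 ± 7.8 Insm1 sites shared with Neurod1 (SD over 10000 placements) and 76.48 ± 9.91 shared with Foxa2. The observed numbers were 278.8-fold and 128.3-fold higher, and no placement reached them (one-sided permutation test, p = 1e-04, the smallest that 10000 placements can give). When partner sites were moved by 10 to 100 kb instead, the observed numbers were 144.8-fold and 79.5-fold higher. The folds over random placement were 41.7 and 22.6 with sites widened by 500 bp, and 488.4 and 235.0 among sites above the median score. Neither kind of placement keeps sites within open chromatin. The folds and p-values therefore cannot tell joint binding from background common to any ChIP in open chromatin.

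Neurod1 sites were more often shared than not. Insm1 was found at 9593 of the 14607 Neurod1 sites (65.67%, 64.9 to 66.44%) and Foxa2 at 8166 (55.9%, 55.1 to 56.71%), against a mean of 57.86 for Foxa2 with random placement (one-sided permutation test, p = 1e-04). The share of Neurod1 sites with Foxa2 was 48.35% with centres within 100 bp and 41.97% with lists of equal length. Both were found at 44.92% of Neurod1 sites. Foxa2 sites more often held neither partner than both. Of the 28379 Foxa2 sites, 16974 (59.81%, 59.24 to 60.38%) held neither partner, 34.59% held Insm1, 28.77% held Neurod1 and 23.18% held both. With each list limited to its 14607 best-scoring sites, a setting chosen after seeing the data, Foxa2 sites with neither partner fell to 46.39% (45.58 to 47.2%), and 34.07% held both.

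**Figure D1:**
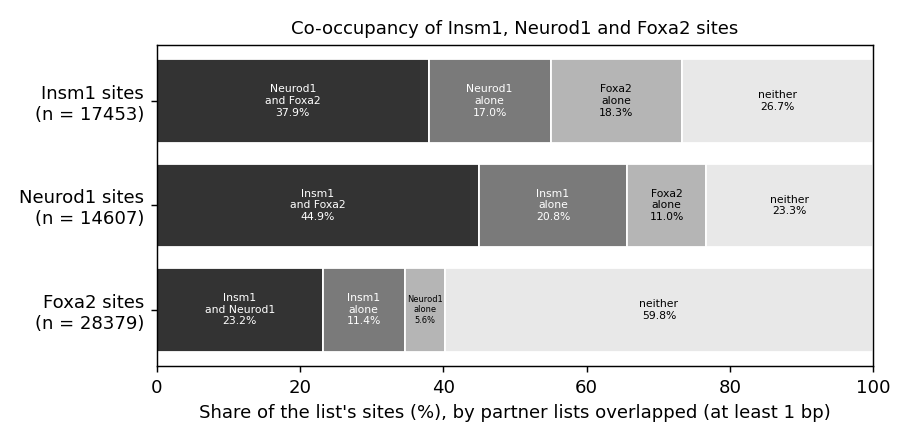
Share of the sites of each list (horizontal axis, %) that overlapped sites of both, one or neither of the other factors by at least 1 bp, 1 bar per list. Both partners were found at 37.95% of Insm1 and 44.92% of Neurod1 sites, and 59.81% of Foxa2 sites held neither.

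Merging all sites gave 39412 regions, of which 6665 (16.9%) held all 3 factors. Random placement gave a mean of 0.25 such regions and at most 5 (one-sided permutation test, p = 1e-04). A further 2957 regions held Insm1 and Neurod1, 3164 held Insm1 and Foxa2, and 1576 held Neurod1 and Foxa2 without Insm1. Foxa2 was alone in 16974 regions, Insm1 in 4667 and Neurod1 in 3409. With only the sites scoring above the median of their list, 3013 regions held all 3 factors.

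The partners met at Insm1 sites more often than their separate shares give. Foxa2 was present at 69.0% of Insm1 sites with Neurod1 and at 40.6% of those without it, an odds ratio of 3.26 (95% interval 3.06 to 3.47, Fisher's exact test). If the 2 partners were independent, 5395 Insm1 sites would hold both, compared with the 6623 counted. The odds ratio was 2.4 (2.24 to 2.57) within deciles of the Insm1 score, and ranged from 1.92 to 2.66 between deciles. In the other lists, for other pairs of partners, the odds ratio was larger, but it was not taken within deciles of score there. Among Neurod1 sites the odds ratio of Insm1 with Foxa2 was 4.6 (4.27 to 4.95), and among Foxa2 sites that of Insm1 with Neurod1 was 21.69 (20.3 to 23.18). Neurod1 was present at 67.0% of Foxa2 sites with Insm1 and at 8.6% of those without it.

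Whether Insm1 met one partner more often than the other depended on how the lists were set side by side. In the full lists the Neurod1 share was 1.28 percentage points below the Foxa2 share (difference -1.28, 95% interval -2.16 to -0.4, exact McNemar test, p = 0.00468). The Foxa2 list is nearly as long as the other lists together. When each list was limited to its 14607 best-scoring sites, a setting chosen after seeing the data, 60.55% of Insm1 sites held Neurod1 and 45.71% held Foxa2, a difference of 14.84 points (13.88 to 15.81, exact McNemar test, p = 2.7e-192). That setting removes sites from the Insm1 and Foxa2 lists at once. Limiting the Foxa2 list alone gave 12.68 points (11.8 to 13.56, exact McNemar test, p = 3.0e-170), and limiting the Insm1 list alone gave 0.97 points (0.02 to 1.93, exact McNemar test, p = 0.0478). Limiting the Foxa2 list can only lower the Foxa2 share, so the direction of that change was fixed in advance. With centres within 100 bp as the rule for sharing, the shares were 51.42% for Neurod1 and 48.25% for Foxa2, and the difference was again the other way, at 3.17 points (2.26 to 4.08, exact McNemar test, p = 9.9e-12).

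Sites with both partners had the highest median score in all 3 lists. Insm1 sites with both partners had a median score of 168, compared with 139 with Neurod1 alone, 113 with Foxa2 alone and 106 with neither. The difference from sites with neither was 62 (95% interval 60 to 65) with both partners, 33 (30.0 to 35) with Neurod1 alone and 7 (5 to 9) with Foxa2 alone. A site with both partners outscored a site with neither in 80.7% of pairs (79.9 to 81.5%). All 3 differences passed the test (two-sided permutation test of ranks, adjusted p = 1.1e-05, the smallest that 100000 resamples give after adjustment over 9 comparisons).

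Among Neurod1 sites the median score was 90 with both partners, 70 with Insm1 alone, 60 with Foxa2 alone and 60 with neither. The first 2 classes were higher than sites with neither by 30 (28 to 31) and by 10 (8 to 11) (two-sided permutation test, adjusted p = 1.1e-05). Neurod1 sites with Foxa2 alone outscored those with neither in 50.6% of pairs (48.9 to 52.3%), which did not pass the test (permutation test, adjusted p = 0.514). That share was 53.0% with centres within 100 bp, 52.3% with widened sites and 52.9% with lists of equal length, and passed the test in each. It was 51.6% among sites above the median score (permutation p = 0.186) and 50.3% without sites of at most 60 bp (permutation p = 0.724), and did not pass. Foxa2 sites had a median score of 85 with both partners, 56 with Insm1 alone, 47 with Neurod1 alone and 34 with neither, and each of the first 3 classes was higher than the last (permutation test, adjusted p = 1.1e-05). In the narrowest tercile of sites the gain with both partners fell to 11 in the Neurod1 list and 26 in the Foxa2 list, from 30 and 51.

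Sharing rose with score across each list. In the lowest decile of Insm1 sites, with scores of 76 to 87, 23.7% (21.8 to 25.8%) held Neurod1 and 38.8% (36.5 to 41.1%) held Foxa2. In the highest decile, with scores of 265 and above, 89.6% (88.1 to 90.9%) held Neurod1 and 81.8% (80.0 to 83.6%) held Foxa2, and 75.0% held both. The share of Neurod1 sites with Insm1 was 43.2% in the lowest decile and 90.1% in the highest. Foxa2 sites with Insm1 made up 13.3% of the lowest decile and 80.2% of the highest, compared with 34.59% of the whole list.

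**Figure D2:**
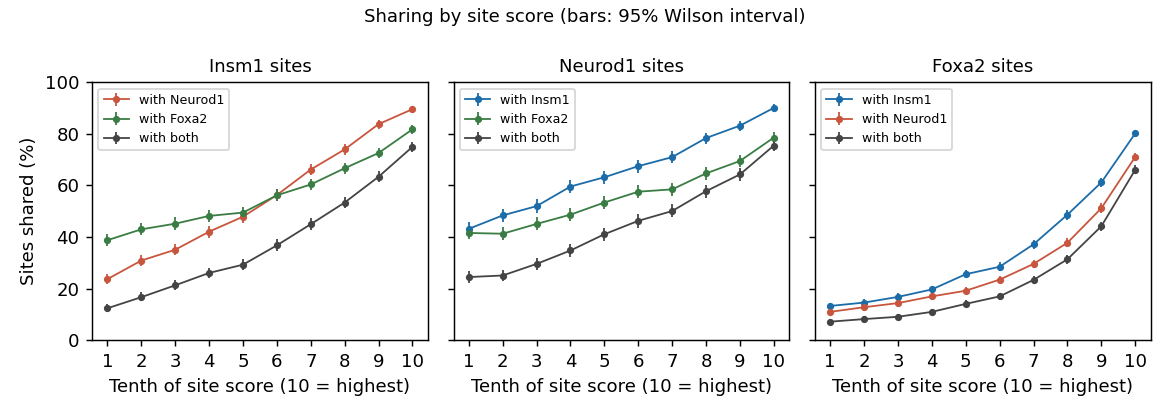
Share of sites overlapping the other factors (vertical axis, %) by decile of the site score within each list (horizontal axis, 10 is the highest), 1 panel per list, with 95% Wilson intervals. Insm1 sites holding both partners went from 12.4% in the lowest decile to 75.0% in the highest.

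Summits lay close together at shared sites, as overlap of narrow sites requires, and the median distance was smallest for Insm1 and Neurod1. The median distance was 31 bp (95% interval 30 to 31 bp) between Insm1 and Neurod1 at 9593 sites, 40 bp (39 to 41 bp) between Insm1 and Foxa2 at 9816 sites, and 41 bp (40 to 42 bp) between Neurod1 and Foxa2 at 8166 sites. Summits lay within 25 bp of each other at 43.7%, 35.2% and 35.0% of these sites. Permuting the relative summit positions among the shared sites gave medians of 33.0, 43.2 and 44.1 bp (one-sided permutation test, p = 1e-04 for each pair, the smallest that 10000 permutations can give). The permuted medians were thus only a few bp larger, and the permuted shares within 25 bp were 39.5%, 30.9% and 30.2%. Insm1 and Neurod1 were the closest pair after permutation too, so their rank does not show closer positions within sites. At the 6623 Insm1 sites with both partners, the Neurod1 summit was the nearer in 3760 and the Foxa2 summit in 2757, with 106 ties (57.7% Neurod1, 56.5 to 58.9%, exact binomial test, p = 1.7e-35). Neurod1 sites are narrower than Foxa2 sites, which limits how far their summits can lie.

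**Figure D3:**
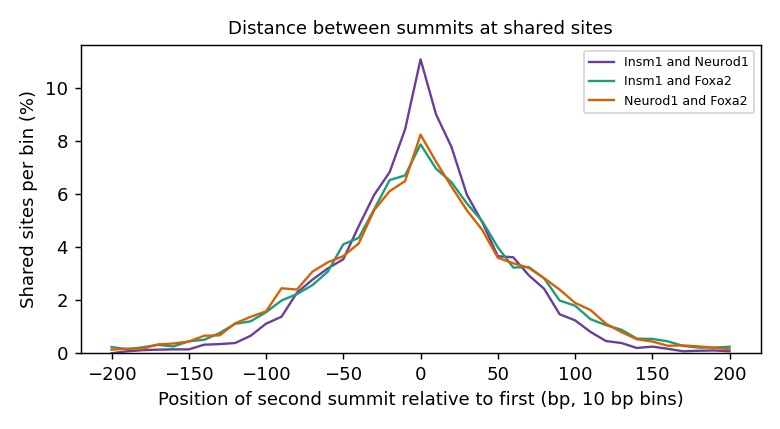
Position of the second factor's summit relative to the first (horizontal axis, bp, 10 bp bins) as a share of the sites shared by each pair (vertical axis, %), 1 line per pair. The Insm1 and Neurod1 line is the narrowest, with a median distance of 31 bp.

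Scores at shared sites rose together, most so for Insm1 and Neurod1. Across shared sites, which are not independent replicates, Spearman's rho was 0.47 (0.46 to 0.49) for Insm1 and Neurod1, 0.34 (0.32 to 0.35) for Insm1 and Foxa2, and 0.29 (0.27 to 0.31) for Neurod1 and Foxa2. Each of the 3 gave a two-sided permutation p = 1e-05, the smallest that 100000 permutations can give, and adjustment over the 3 pairs leaves it unchanged.

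The strongest Insm1 site with both partners lay on chromosome 7 at 140799666 to 140799849, with an Insm1 score of 3005, and its Neurod1 and Foxa2 sites ranked 2485 and 1364 in their lists. The next was a 52 bp site on chromosome X at 100388287 to 100388339 (Insm1 score 2325), which was also the highest-scoring Neurod1 site (1523). The others were on chromosome 10 at 61806751 to 61806943 (2050), on chromosome 10 at 89289756 to 89289917 (1705) and on chromosome 2 at 103176973 to 103177128 (1577). The top of the Insm1 list was a 52 bp site on chromosome 1 at 197067782 to 197067834 (score 3106) that held neither partner. Both 52 bp sites fall in the class of at most 60 bp that was tested as stacks of reads. The X-linked one had the same start and end in the Neurod1 list, and its Foxa2 site ranked 26. Joint binding at the X-linked site cannot be told from such a stack.

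After the X-linked site, the highest Neurod1 sites lay on chromosome 10 at 111106795 to 111106970 (score 1428), on chromosome 19 at 61275633 to 61275701 (1420), on chromosome 13 at 118024495 to 118024663 (1299) and on chromosome 17 at 39981114 to 39981338 (1133). Those on chromosomes 10 and 13 held both partners and their Insm1 sites ranked 81 and 25 in the Insm1 list, the one on chromosome 19 held Foxa2 alone and the one on chromosome 17 held neither. The 5 highest Foxa2 sites were 52 or 53 bp wide and held neither partner. Binding cannot be told from stacks of reads at these 5 sites. They lay on chromosome 2 at 98507267 to 98507319 (score 404994), 98502404 to 98502456 (82289) and 98505220 to 98505273 (11791), on chromosome 6 at 103599180 to 103599232 (43944) and on chromosome X at 139917590 to 139917642 (27155). Among Foxa2 sites wider than 60 bp with both partners, chosen after the values were seen, the highest lay on chromosome 16 at 69980201 to 69980458 (score 1120), where the Insm1 site ranked 24 and the Neurod1 site 248.

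Sites of all 3 factors were sparse on the X chromosome. Autosomes carried 7.18 Insm1, 5.99 Neurod1 and 11.51 Foxa2 sites per Mb, and the X chromosome 1.06, 1.11 and 3.99. The X density was thus 14.7% of the autosomal density for Insm1, 18.6% for Neurod1 and 34.7% for Foxa2. Sites on X made up 0.97% (0.84 to 1.13%) of Insm1 sites, 1.23% (1.06 to 1.42%) of Neurod1 sites and 2.27% (2.1 to 2.45%) of Foxa2 sites. The odds ratio of Foxa2 against Insm1 was 2.36 (1.99 to 2.79, Fisher's exact test, adjusted p = 1.1e-25 over 3 comparisons), and that of Neurod1 against Insm1 was 1.26 (1.02 to 1.56, Fisher's exact test, adjusted p = 0.0349). Among autosomes the Insm1 density was lowest on chromosome 6 (5.62 per Mb) and highest on chromosome 11 (9.64 per Mb), and Neurod1 had its lowest and highest densities on the same 2 chromosomes (4.49 and 8.19 per Mb).

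**Figure D4:**
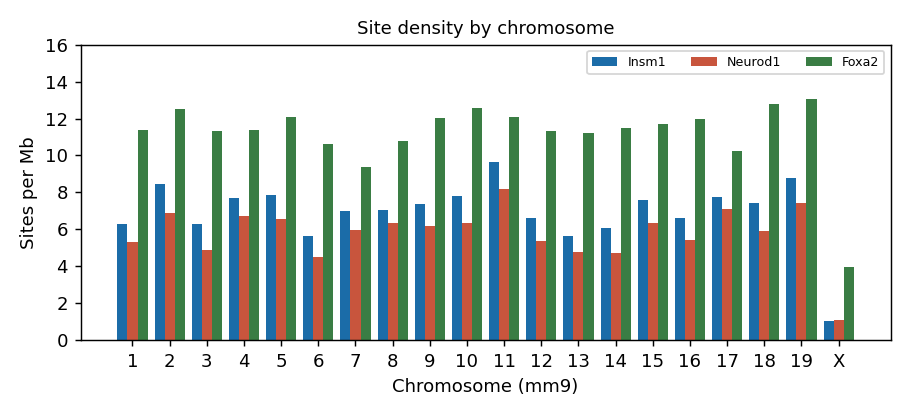
Sites per Mb (vertical axis) of the span between the first and last site of each chromosome (horizontal axis), 1 bar per factor. On X the densities were 1.06 for Insm1, 1.11 for Neurod1 and 3.99 for Foxa2, under those of every autosome.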

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

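The comparisons in this part were chosen after the site lists had been seen, as were the tests of equal list length and of narrow sites.

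The X-linked share differed between factors under the same contrast of X against autosomes, with an odds ratio of 2.36 (1.99 to 2.79) for Foxa2 against Insm1 sites. The greater length of the Foxa2 list was tested with lists of equal length, and the odds ratio stayed at 2.26 (1.83 to 2.77) and was 2.07 (1.72 to 2.51) with the Foxa2 list alone limited, so list length is not the whole cause. Stacks of reads at narrow sites were tested by removing sites of at most 60 bp, and the odds ratio was 2.29 (1.93 to 2.72), so these sites are not the cause either. The number of X copies in the line, the threshold used for each list and the mappability of X were not tested. A true difference in where the factors bind stays open and untested.

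The gain in score with Foxa2 as the only partner differed between the Insm1 and Neurod1 lists. Insm1 sites with Foxa2 alone stood 6.68 score percentiles above Insm1 sites with neither, and the same contrast gave 0.57 among Neurod1 sites, a difference of 6.1 (permutation of the list labels within each class, p = 1e-05, the smallest that 100000 resamples can give). The Neurod1 side depended on the setting, since the share of pairs in which a Neurod1 site with Foxa2 alone outscored one with neither went from 50.6% to between 52.3 and 53.0% with 3 other settings and was 51.6 and 50.3% with the remaining settings, and the corresponding Insm1 share stayed between 56.1 and 57.1%. The difference of 6.1 was not recomputed under those settings, and no explanation of it was tested.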

How the results depend on the processing

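Over 16 results and 93 alternative values, 72 kept their direction and their side of the threshold, or stayed within 1.5 times the main value for counts and within the interval for shares with no test. This tally does not measure how stable the sizes were. With this many sites most p-values lay far under the threshold, and local moves reuse the main counts. In the narrowest tercile the Neurod1 score gain with both partners fell from 30 to 11 and the Foxa2 gain from 51 to 26. Both were counted as kept. The tests with lists of equal length or a single list limited, without sites of at most 60 bp and within deciles of score, the alternatives for the Neurod1 and Foxa2 scores and for sites with neither partner, and the tests of the X-linked share, of summits, of scores with Foxa2 alone and of the Neurod1 minus Foxa2 share, were chosen after seeing the data. The number of regions with all 3 factors was 3013 among sites scoring above the median of their list, where each list holds fewer sites by construction. The Neurod1 minus Foxa2 share of Insm1 sites reversed from -1.28 points to 3.17 with centres within 100 bp, to 14.84 with lists of equal length, to 12.68 with the Foxa2 list alone limited to 14607 sites and to 0.97 with the Insm1 list alone limited. The length of the Foxa2 list, low-scoring Insm1 sites and site width are candidate explanations. The difference was -2.87 with widened sites, -2.78 among sites above the median score and -1.72 without sites of at most 60 bp. The Foxa2 list stayed the longest in each of these settings. Sites with neither partner made up 26.74% of Insm1, 23.34% of Neurod1 and 59.81% of Foxa2 sites. These shares were 31.31, 27.22 and 63.82% with centres within 100 bp, 22.72, 17.45 and 55.6% with sites widened by 500 bp, 29.07, 27.1 and 60.81% among sites above the median score, and 27.99, 31.48 and 46.39% with lists of equal length. Without sites of at most 60 bp the Neurod1 share was 22.17%. Wider rules for sharing and longer partner lists give fewer such sites by construction, and other causes were not tested. The share of pairs in which a Neurod1 site with Foxa2 alone outscored one with neither passed the test at 53.0% with centres within 100 bp, 52.3% with sites widened by 500 bp and 52.9% with lists of equal length, but not at 51.6% among sites above the median score or 50.3% without sites of at most 60 bp, and the cause was not tested. The share of Insm1 sites with Neurod1 ranged from 51.25 to 60.55% and with Foxa2 from 42.28 to 61.12%, that of Neurod1 sites with Foxa2 from 41.97 to 63.21%, the odds ratio between the partners from 2.4 to 3.33, and the Insm1 score gain with both partners from 42 to 70. Local moves of partner sites left each of the 4 placement results past the threshold, with lower folds over random placement (144.8 against 278.8 for Insm1 with Neurod1, 79.5 against 128.3 with Foxa2). Not run were another score column, since the lists hold 1 score, and the planned comparisons of promoters, gene lists and motifs, which need mm9 annotation or sequence. With 1 list per factor, leaving out a replicate was not possible. Read depth per site is unknown, so weak partner binding under a list's threshold cannot be told from its absence.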

Other observations

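The tests of neighbouring sites, X-linked sharing, narrow sites, list length, common background and the Neurod1 against Foxa2 share were chosen only after the data were seen, and the local moves, a setting fixed earlier, were set against regional clustering only after their result was seen.

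Insm1 sites clustered, and sites with both partners did so more. Another Insm1 site lay within 10 kb of 25.5% of Insm1 sites, compared with 13.5% for sites placed uniformly along each chromosome (at most 14.6% in 1000 draws). The share was 28.6% for Insm1 sites with Neurod1 and Foxa2 and 21.5% for those with neither (odds ratio 1.46, 1.34 to 1.59, Fisher's exact test, p = 1.9e-17). Neighbouring sites count for each other and are not independent, so the interval may be too narrow and the p-value too small. Chained at 10 kb, 3 clusters held 6 Insm1 sites, and these and the next were chosen after their values were seen. They lay on chromosome 2 at 147787454 to 147825860, where 5 of the 6 held both partners, on chromosome 7 at 30768699 to 30794961, where 4 did, and on chromosome 4 at 149494381 to 149513413, where 2 did and one site reached an Insm1 score of 1225. A cluster of 5 Insm1 sites on chromosome 11 at 48630594 to 48651575 held no site with both partners.

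On the X chromosome, the few Insm1 sites met Foxa2 more often than on autosomes, at 71.8% (64.6 to 78.0%) against 56.1% (55.3 to 56.8%), with an odds ratio of 1.99 (1.42 to 2.78, Fisher's exact test, p = 3.4e-05). For Insm1 sites with Neurod1 the shares were 57.6% and 54.9% (Fisher's exact test, p = 0.487). Seen from the Neurod1 list, 54.7% of X-linked sites and 65.8% of autosomal sites held Insm1 (odds ratio 0.63, 0.47 to 0.84, Fisher's exact test, p = 0.00252). Seen from the Foxa2 list, 19.0% of X-linked sites held Insm1 and 35.0% of autosomal sites did. On X there were 643 Foxa2 and 170 Insm1 sites, against 27730 and 17283 on autosomes. The shares seen from the Insm1 and Foxa2 lists count the same overlaps and depend on this ratio, so they are not separate results. The p-values for X-linked sharing were not adjusted for the number of tests.

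The highest Foxa2 scores belonged to very narrow sites. Of the 20 highest-scoring Foxa2 sites, 18 were at most 60 bp wide, compared with 2 of 20 for Insm1 and 1 of 20 for Neurod1. Among the highest decile of Foxa2 sites, 12 of the 48 narrow sites (25.0%) and 2403 of the 2789 wider sites (86.2%) met at least 1 partner (Fisher's exact test, p = 5.4e-21). Narrow sites were less often shared in the other lists too. The shares were 68.4% of 19 narrow and 96.8% of 1726 wider sites for Insm1, and 61.1% of 18 and 93.7% of 1442 for Neurod1. Few sites were on chromosome Y (0 of Insm1, 2 of Neurod1, 5 of Foxa2) or the mitochondrial genome (0, 1 and 1).

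The coincidence of the 3 factors was weighed against 3 technical explanations. Regional clustering of sites was tested by moving partner sites by 10 to 100 kb. A mean of 66.26 Insm1 sites with Neurod1 was left of the 9593 counted, so clustering at that scale does not account for the sharing. Each site was moved by at least 10 kb, so clustering at finer scales was not tested. Sites of at most 60 bp do not account for it either, since one in either list was involved at 124 of the 9593. Without such sites, 54.48% of Insm1 sites held Neurod1 and 56.2% held Foxa2, and 56.97% of Neurod1 sites held Foxa2. Stacks of reads wider than 60 bp were not tested. Background common to any ChIP in open chromatin cannot be told apart from joint binding here, because no IgG site list was analysed. Neurod1 sites with Foxa2 alone outscored those with neither in 50.6% of pairs (permutation p = 0.514). That share was 53.0, 52.3 and 52.9% under 3 settings that passed the test and 51.6 and 50.3% under those that did not. Seen from the Foxa2 list, sites with Neurod1 alone outscored those with neither in 63.6% of pairs. The other classes with a single partner gave 56.7 to 71.1% (permutation test, adjusted p = 1.1e-05 for each of these classes). These values do not decide the question. Joint binding of the factors at the same elements stays a hypothesis.

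The slight excess of Foxa2 over Neurod1 at Insm1 sites may reflect the lists and not the cells. A longer Foxa2 list is one candidate explanation. With the Foxa2 list alone limited to 14607 sites, the Neurod1 share was 12.68 points (11.8 to 13.56) above the Foxa2 share. Limiting that list can only lower the Foxa2 share, so the size of this change was open but its direction was not. Low-scoring Insm1 sites are another candidate, since with the Insm1 list alone limited the difference was 0.97 points (0.02 to 1.93), close to 0. Wider Foxa2 sites are also a candidate, since with centres within 100 bp the difference was 3.17 points in favour of Neurod1. In other settings Foxa2 stayed ahead. The Neurod1 minus Foxa2 difference was -2.78 points (-4.05 to -1.52) among sites above the median score of each list. It was -2.87 points with sites widened by 500 bp and -1.72 points without sites of at most 60 bp. The Foxa2 list stayed the longest in each of these settings, so they cannot speak against list length. The setting above the median score also shortens the partner lists, so it does not isolate low-scoring Insm1 sites. Against the full partner lists, the lowest decile of Insm1 sites held Foxa2 more often (38.8% against 23.7% for Neurod1). The highest decile held Neurod1 more often (89.6% against 81.8%). These readings rest on 1 list per factor, and which partner Insm1 meets more often in these cells stays open.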
